A study of Rattus norvegicus with 30 samples.

How the data were processed

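RNA from the oesophageal epithelium of 30 male Sprague-Dawley rats was measured on Affymetrix rat expression arrays, 1 array per rat. Per the labels, rats were placed on a zinc-deficient (ZD, fed ad libitum) or zinc-sufficient (ZS, pair-fed) diet at 4 weeks of age and received 4 doses of 2 mg/kg NMBA starting in week 5, with tissue taken 15 weeks after the first dose. AntimiR rats received a loading dose of 20 mg/kg and 9 maintenance doses of 6 mg/kg over 5 weeks, and the 20-week group a further 20 doses. The labels leave open whether the 5-week group was sampled at the same age as the others. Per the labels, the knockout rats came from a separate experiment with the same NMBA treatment.

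The deposited values are log2 expression values per probe set, which the authors produced, per the submitters' processing notes, with Affymetrix Expression Console and RMA; the versions were not given in the sources used here. The table holds 31099 probe sets on 30 arrays. Array medians fell into 2 sets, one of 20 arrays from unedited rats and one of 10 knockout arrays, and the sets were taken as normalized separately. Values ran from about 2.11 to 14.5 log2 units.

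Of the probe sets, 20826 carried 1 gene symbol, 436 several and 9780 none that was used, and 57 were controls. Of those with 1 symbol, 20758 matched the reference table by gene ID. For each of the 14217 genes the probe set with the highest mean value over all arrays was used, and 4525 genes had more than 1. Linear models were fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with 1 coefficient per group and moderated t tests, and p values were adjusted by the Benjamini-Hochberg method within a comparison with a threshold of 0.05. The comparisons were ZD against ZS in unedited and in knockout rats, each antimiR group against untreated ZD, 20 against 5 weeks of antimiR, knockout against untreated on each diet, and the diet by genotype interaction. Sample numbers are unique to each rat, so no pairing was used.

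The 19 gene lists were fixed before the data were examined: published miR-31 targets, NF-kB targets and inflammation, neutrophil and mast cell, macrophage and antigen presentation, T and B cell, cell cycle, cornified envelope, basal and stress keratins, zinc transport and metallothionein, hypoxia and glycolysis, Nrf2 and xenobiotic response, interferon response, immediate early, skeletal muscle, smooth muscle, fibroblast and matrix, endothelial, adipocyte, and erythroid genes. They were tested with camera in limma, with a preset inter-gene correlation of 0.01, adjusted over 152 tests, and again with the correlation estimated per list. The direction of this test is relative to the other genes. Genes of a list were also adjusted over the list alone.

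Genes were named by a rule fixed before the data were examined: per comparison the 10 largest increases and 10 largest decreases that passed and whose groups did not overlap (for the interaction, that passed), without symbols that only name a locus; up to 4 members of each list with the smallest adjusted p; and Egln3, Stk40, S100a8, S100a9, Ptgs2, Mki67, Krt14, Krt13 and Slc39a4. Where the same untreated ZD arrays served both sides of an overlap, 100 simulated draws without an antimiR effect and 10 splits of those arrays gave the values to compare with. To see how many genes other groupings give, 100 splits of the arrays were used, the real one included.

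The alternatives were quantile normalization across the 30 arrays, median centring, leaving out the dimmest 30% of genes, eBayes with trend and robust fitting, array weights, only the groups compared, the mean of all probe sets of a gene, all probe sets, skeletal muscle level as a covariate and leaving out each array in turn. Smooth muscle level as a covariate and only arrays of the same normalization set were added after the data were seen. The fit was tested on simulated data: of 100 genes changed by 1 log2 unit, 91 were recovered for diet in unedited rats, 90 for 20 weeks of antimiR, 89 for diet in knockout rats and 79 for the interaction. Of 50 changed by 0.5, 37, 36, 34 and 24 were recovered. The simulated noise was independent between genes, with a single spread per gene for all groups. It therefore leaves out genes that move together and arrays that stand apart, and recovery in the real data may be lower. With 4 to 6 arrays per group, the number of arrays limits precision, and changes of 0.5 were often missed. Smaller changes were not simulated.

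A test of miR-31 seed sites was planned and not run, since no transcript sequence was available here, and wild-type littermates of the knockout rats were not analysed here.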

Results

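Transcript levels were measured in the oesophageal epithelium of 30 male rats, 1 array per rat, after treatment with N-nitrosomethylbenzylamine (NMBA), a carcinogen of the rodent oesophagus. Of the rats without a gene edit, 5 were fed a zinc-deficient (ZD) diet and 5 a zinc-sufficient (ZS) diet without other treatment. A further 5 ZD rats received a locked nucleic acid oligonucleotide against the microRNA miR-31 (antimiR) over 5 weeks and 5 over 20 weeks. The remaining 10 rats were miR-31 knockouts made with CRISPR, per the labels, 6 on ZD and 4 on ZS; miR-31 itself was not measured on the arrays. The median array value lay between 5.37 and 5.45 log2 units on the 20 arrays of unedited rats and between 5.81 and 5.93 on the 10 knockout arrays. Within a group, the correlation between any pair of arrays was at least 0.977. Changes below are on the log2 scale with the standard error (SE) of the fitted change, and a gene is said to rise or fall only where its limma adjusted p passed 0.05 over the 14217 genes tested. Most genes were named by a rule fixed beforehand. Chosen after their values were seen were Ndrg1, Hk2, Ldha, Cxcl1, Cxcl2, Il1b, Tagln, Des, Ppp6c, Smad4, Rasa1, Akr1b8, Aldh1a1 and Ppl for diet in unedited rats, Cdk1, Car2 and Krt6c for antimiR, and Csf1r, Fn1, Col1a2, Actg2, Sprr2d, Tmprss11d, Klf2 and Ptges for knockout rats. Genes given as examples of an overlap were also chosen that way.

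In rats without antimiR, expression of Car2, Ptgs2, Krt6c and Krt17 rose on zinc deficiency and that of Aox4, Upk1b and Myh11 fell (n = 5 on each diet). Car2, which encodes a carbonic anhydrase, rose by 4.56 (SE 0.65, adjusted p = 0.000101), from a mean of 5.77 (SD 0.88) on ZS to 10.33 (SD 1.13) on ZD. Ptgs2, the inducible cyclooxygenase, rose by 3.87 (SE 0.68, adjusted p = 0.000612). Of its ZD arrays, 4 lay between 6.86 and 9.14, and array 15 lay at 3.15, inside the ZS range of 3.04 to 3.26. The keratin genes Krt6c and Krt17, induced in wounded and dysplastic epithelium, rose by 3.57 (SE 0.52) and 3.22 (SE 0.61). Aox4, an aldehyde oxidase, fell by 3.88 (SE 0.73, adjusted p = 0.00107).

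The serpin Serpinb3 rose by 4.15, the cystatin-like protease inhibitor Stfa2l2 by 3.07 and the cornified envelope precursor Sprr1b by 2.35. S100a8, a subunit of the inflammatory protein calprotectin, rose by 3.99 (SE 0.98, adjusted p = 0.00792), whereas its partner S100a9 did not pass at 3.10 (SE 1.12, adjusted p = 0.0643). The P-type ATPase Atp13a5 rose by 2.86, the tissue plasminogen activator gene Plat by 2.30, the homeobox gene Irx4 by 2.30, the tubulin gene Tubb3 by 2.13 and the airway-type protease gene Tmprss11d by 2.04. A second probe set of Irx4 and of Tubb3 moved little, by 0.02 and 0.03. The decreases included the uroplakin Upk1b at -2.89, the ion transport regulator Fxyd4 at -2.85, the alcohol dehydrogenase Adh6a at -2.77 and Prr15 at -2.53. The proliferation marker Mki67 (0.29, adjusted p = 0.712), the suprabasal keratin Krt13 (adjusted p = 0.997), the basal keratin Krt14 (0.51, adjusted p = 0.0686) and the zinc importer Slc39a4 (-0.02, adjusted p = 0.944) did not pass.

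**Figure D1:**
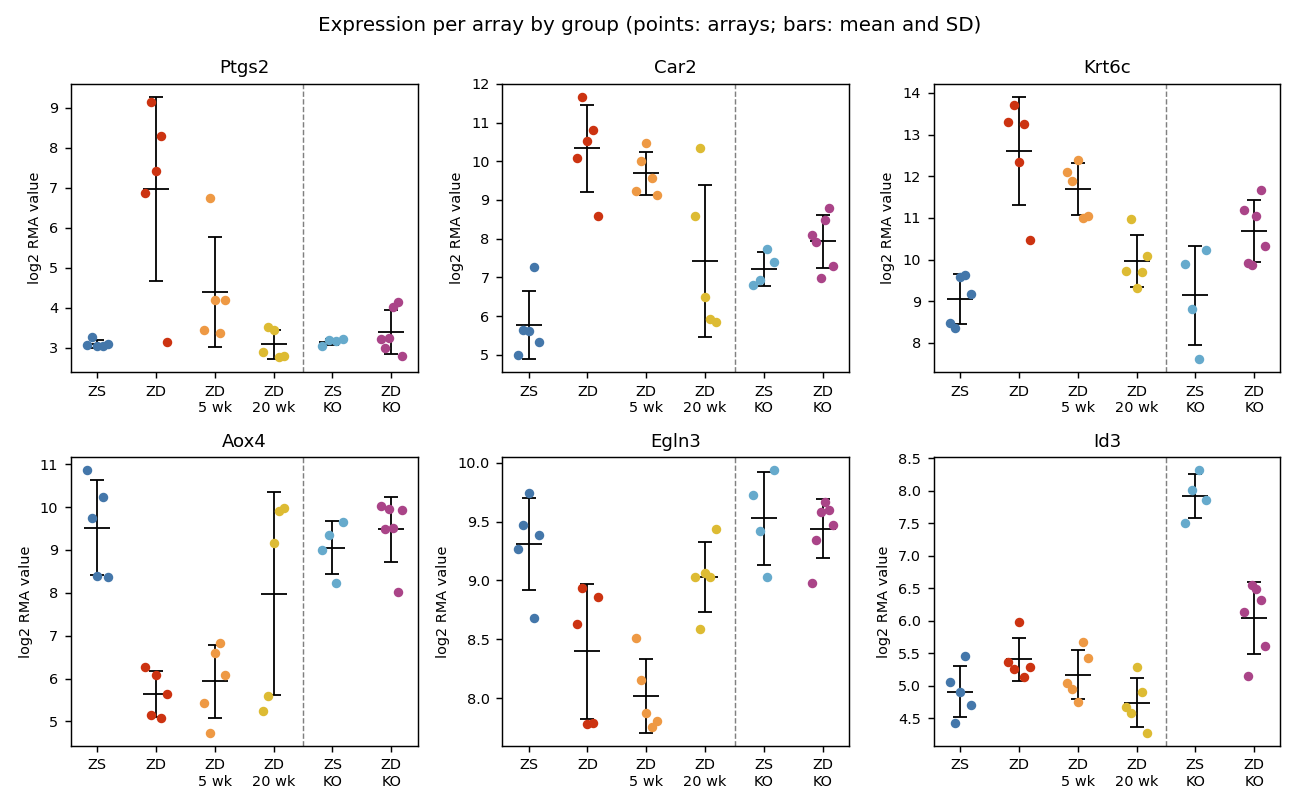
Points are log2 RMA values of single arrays for Ptgs2, Car2, Krt6c, Aox4, Egln3 and Id3 in the 6 groups, bars are the group mean and SD, and the dashed line sets off the knockout arrays. Ptgs2 was between 6.86 and 9.14 on 4 of the 5 untreated ZD arrays and no higher than 4.14 on any of the 6 ZD knockout arrays.

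Of the 14217 genes, 1974 changed between the diets in these rats, 986 up and 988 down, and 100 rose and 185 fell by at least 2-fold. Leaving out ZD array 14 lowered the number to 1191, and leaving out ZD array 15 raised it to 2424. Each of the 20 genes named by rank, from Car2 and Serpinb3 to Aox4 and Synpo2, passed in all 10 fits that left out 1 array. A fit added after the data were seen used the mean smooth muscle level of each array as a covariate. It called 181 genes, 135 of them among the 1974. This covariate itself differed with diet, with a mean of 7.90 on ZD and 9.56 on ZS. The fit therefore also removes diet effect, and a lost call does not show that a gene follows smooth muscle content. In that fit 5 of the 20 still passed, among them Car2 (3.20, adjusted p = 0.0367), Krt6c (2.56, adjusted p = 0.0421) and Irx4 (1.87, adjusted p = 0.00648), and Aox4 stood at -1.84 (adjusted p = 0.241). Of all 58 called genes named by the rule 15 passed with the covariate; Ptgs2 (2.34, adjusted p = 0.141), Krt17 (2.46, adjusted p = 0.113) and S100a8 (1.25, adjusted p = 0.614) did not.

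Of the genes of glycolysis and the hypoxia response 13 of 27 measured members rose on ZD (16 adjusted over the list alone), none fell and 14 did not pass. The list median was 0.42 (camera adjusted p = 4.96e-07 with a preset correlation, adjusted p = 0.332 with an estimated correlation), and 0.24 with the smooth muscle covariate. The genes that rose included the mitophagy gene Bnip3 at 1.40 (SE 0.23), the vasoactive peptide gene Adm at 1.48, Ndrg1 at 1.38, the hexokinase Hk2 at 1.13, the glucose transporter Slc2a1 at 0.90, the angiogenic factor Vegfa at 0.82 (SE 0.13) and Ldha at 0.74. Among NF-kB targets and inflammatory genes 8 of 32 rose (12 adjusted over the list alone) and none fell: beside Ptgs2 and S100a8 these were the chemokine genes Ccl2 at 2.45, Cxcl1 at 1.68 and Cxcl2 at 1.21, the prostaglandin E synthase Ptges at 1.19, Il1b at 0.95 and the inhibitor Nfkbia at 0.60. The median of that list was 0.26 (adjusted p = 0.00014, and adjusted p = 0.507 with an estimated correlation), and 0.10 with the smooth muscle covariate (adjusted p = 0.0447, the highest over 20 alternatives).

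Smooth muscle genes fell together on ZD: 11 of 14 fell (13 adjusted over the list alone), with a list median of -1.68 (adjusted p = 7.47e-10, and adjusted p = 0.525 with an estimated correlation). The calponin gene Cnn1 fell by 2.59 (SE 0.54), the myosin heavy chain Myh11 by 2.56 (SE 0.50), Actg2 by 2.35, Synpo2 by 2.34, Tagln by 2.33, Mylk by 2.27 and Des by 1.71. Myl9, a further contractile gene outside the list, fell by 2.46. The array means of the list ran from 7.46 to 8.43 on ZD and from 9.03 to 10.4 on ZS. Other tissue markers moved less. Fibroblast and matrix genes had a median of -0.32 (adjusted p = 0.337), with the collagen cross-linking enzyme Lox rising by 1.95; with the smooth muscle covariate the median turned to 0.42 and the list passed (adjusted p = 4.15e-05). Skeletal muscle genes had a median of -0.14 (adjusted p = 0.688). Endothelial genes had a median of 0.25 (adjusted p = 0.0541), with the VEGF receptors Flt1 and Kdr rising by 0.71 and 0.68. Kdr lost the threshold without ZD array 12, 13 or 14 or ZS array 18 or 19 (adjusted p up to 0.0783). The endothelial list passed when ZD array 11, 12 or 14 or ZS array 19 or 20 was left out (adjusted p from 0.0174 to 0.0489) and under most other alternatives, with a median of 0.68 with the smooth muscle covariate (adjusted p = 6.76e-10). Of single genes in the other tissue lists, the macrophage lysozyme Lyz2 rose by 1.24, the lipase Lpl by 1.15 and the beta globin Hbb by 1.62. Lyz2 lost the threshold in 9 of the 10 fits that left out 1 array, in all but the one without ZS array 16 (adjusted p up to 0.0893).

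Published miR-31 targets were lower on ZD as a list: 8 of 40 fell (9 adjusted over the list alone) and 2 rose (3 adjusted over the list alone). The list median was -0.10 (adjusted p = 0.0274, from 0.0145 to 0.213 over 20 alternatives, and adjusted p = 0.577 with an estimated correlation), and -0.06 with the smooth muscle covariate. The prolyl hydroxylase Egln3 fell by 0.91 (SE 0.23, adjusted p = 0.00913), the NF-kB pathway repressor Stk40 by 0.40 (SE 0.08, adjusted p = 0.00175), the deubiquitinase Bap1 by 0.42, the phosphatase Ppp6c by 0.33 and Smad4 by 0.30. The circadian gene Clock and the Ras regulator Rasa1 rose, by 0.43 and 0.37. Without ZS array 19 the median was -0.05 and the list did not pass (adjusted p = 0.054).

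Of the zinc transport and metallothionein genes 5 of 25 rose and 1 fell (7 and 1 adjusted over the list alone): the importer Slc39a10 rose by 1.19 (SE 0.27), the metallothioneins Mt2A and Mt1 by 0.86 and 0.59, and Slc39a2 fell by 1.01 (SE 0.24). Mt2A lost the threshold without ZD array 12 or 14 or ZS array 18 or 20, and Mt1 without ZD array 12 or 14 or ZS array 17 (adjusted p up to 0.124 and 0.0855). The list test gave adjusted p = 0.39. The Nrf2 and xenobiotic list was split, with 5 of 25 up and 4 down (6 and 5 adjusted over the list alone; adjusted p = 0.782). The cystine transporter Slc7a11 rose by 1.52, Akr1b8 by 1.53, the glutathione transferase Gstm1 by 1.24 and Cbr1 by 1.21, while the cytochrome Cyp1b1 fell by 1.56 and the retinal dehydrogenase Aldh1a1 by 1.22. In the cornified envelope list 4 of 31 rose and 3 fell (adjusted p = 0.705), with Sprr1b and Sprr2d (1.63) up and the plakin genes Evpl (-0.50) and Ppl (-0.41) down; Sprr2d lost the threshold without ZD array 14 or ZS array 16 or 20 (adjusted p up to 0.0708). In the basal keratin list 2 of 17 rose and 2 fell (adjusted p = 0.864), with the basement membrane collagen Col17a1 at -0.73. Of 18 immediate early genes Fosl1 rose by 2.01, Junb rose by 0.64 and Egr2 fell by 0.89, with a list median of 0.29 (adjusted p = 0.0407, and adjusted p = 0.803 with an estimated correlation). That call was lost without ZD array 13 or ZS array 16, 19 or 20 (adjusted p from 0.0634 to 0.231), and its adjusted p ran from 0.0186 to 0.691 over 20 alternatives, the latter with the smooth muscle covariate (median 0.19).

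Cell cycle genes had a median of 0.33 on ZD, with 31 of 38 above 0 and no single gene past the limma threshold (list adjusted p = 0.0344, and adjusted p = 0.964 with an estimated correlation). The list call was lost without ZD array 12 (median 0.22), 13 (0.29) or 14 (0.06) and without ZS array 16 (0.33) or 19 (0.31), and its adjusted p ran from 6.93e-06 to 0.53 over 20 alternatives. The macrophage list (median 0.27, adjusted p = 0.107) and the T and B cell list (0.15, adjusted p = 0.39) did not pass, but both did when only the compared groups were fitted (adjusted p = 0.00135 and 0.0189). In the main fit both stood at adjusted p = 0.964 with an estimated correlation. With the smooth muscle covariate the macrophage median was 0.43 (adjusted p = 0.00442). The neutrophil and mast cell list (adjusted p = 0.864), the interferon list (-0.08, adjusted p = 0.71), the adipocyte list (-0.06, adjusted p = 0.737) and the erythroid list (0.01, adjusted p = 0.547) did not pass. The cornified envelope, interferon and adipocyte lists had medians below 0 and means of 0.04. Across all comparisons 152 list tests were made, of which 49 passed with the preset correlation and 0 with an estimated correlation.

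**Figure D2:**
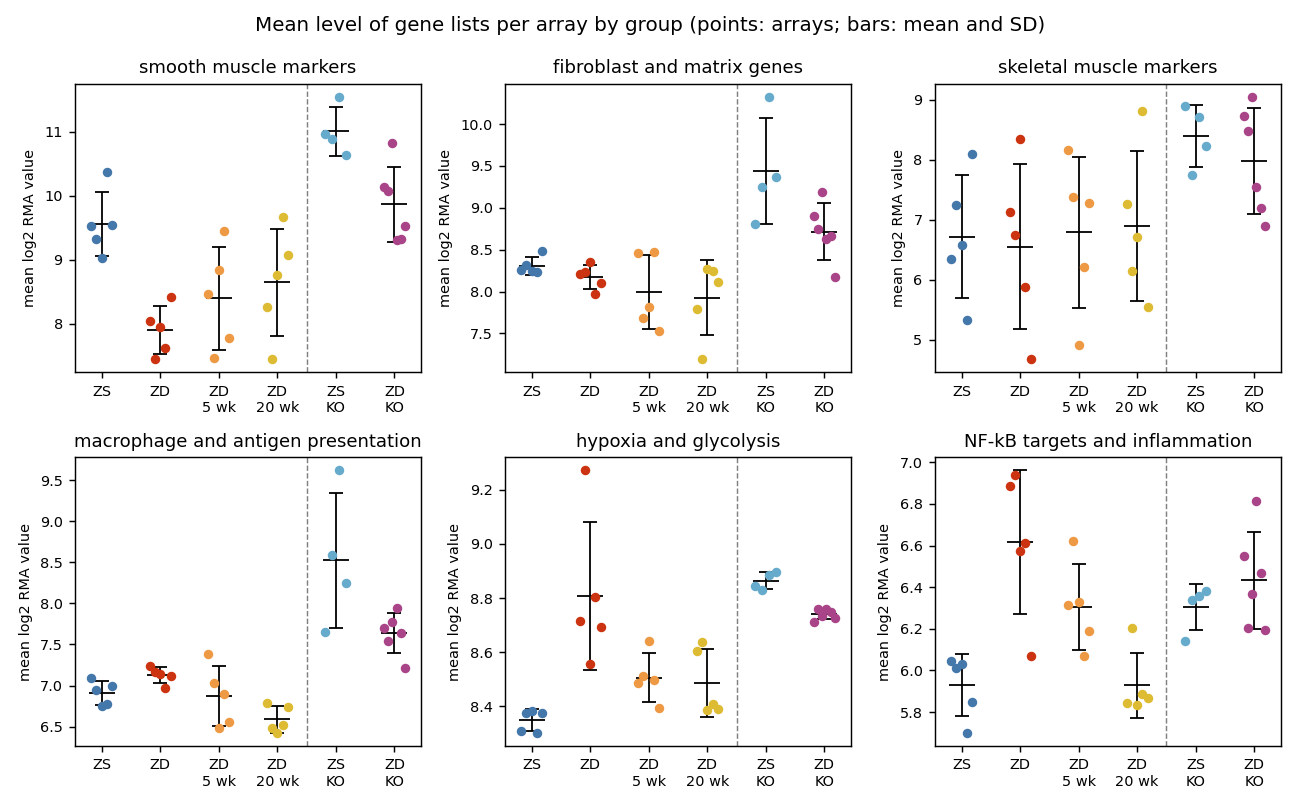
Points are the mean log2 RMA value of the measured members of a gene list on single arrays, bars are the group mean and SD, and the dashed line sets off the knockout arrays. Smooth muscle genes lay between 7.46 and 8.43 on untreated ZD arrays and between 9.03 and 10.4 on untreated ZS arrays, and the macrophage list reached 9.62 on ZS knockout array 32.

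The 5-week antimiR group was compared with untreated ZD rats (n = 5 each). Its antimiR doses were given before and around the start of NMBA. The controls are labelled untreated, so effects of dosing itself cannot be told apart from those of miR-31 inhibition, which was not measured. The labels also leave open whether the 5-week rats were sampled at the same age as the others. No gene passed with limma, the smallest adjusted p was 0.064, and 1021 genes had an unadjusted p under 0.05. As lists, hypoxia genes were lower with a median of -0.26 (adjusted p = 4.15e-09, and adjusted p = 0.264 with an estimated correlation), and 7 of 27 fell when adjusted over the list alone. The median ran from -0.32 to -0.12 over 20 alternatives, the latter without ZD array 12. Cell cycle genes were lower in 38 of 38 members, with a median of -0.40 (adjusted p = 1.13e-07, and adjusted p = 0.803 with an estimated correlation). The median ran from -0.72 without ZD array 15 to -0.18 without ZD array 14. Among these genes, the mitotic spindle gene Hmmr stood at -0.75, Ube2c at -0.67 and Cdk1 at -0.61. The Nrf2 list had a median of -0.19 (adjusted p = 6.21e-05, and adjusted p = 0.264 with an estimated correlation), with the glutathione synthesis gene Gclm at -0.36 and Nqo1 at -0.40; it was -0.13 without antimiR array 7 and -0.12 without ZD array 11. NF-kB targets had a median of -0.15 (adjusted p = 0.000462, and adjusted p = 0.525 with an estimated correlation), and 2 of 32 fell when adjusted over the list alone. The NF-kB call was lost without dim genes (adjusted p = 0.0961), and its adjusted p ran from 1.44e-05 to 0.0961 over 20 alternatives.

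Macrophage genes had a median of -0.30 after 5 weeks of antimiR (adjusted p = 0.00122, and adjusted p = 0.803 with an estimated correlation). Smooth muscle genes were higher with a median of 0.55 (adjusted p = 0.00479, and adjusted p = 0.843 with an estimated correlation), a call that was lost without antimiR array 9 (median 0.28, adjusted p = 0.344) and with the smooth muscle covariate, and its adjusted p ran from 1.48e-05 to 0.976 over 20 alternatives. Ptgs2 was -2.58 (SE 0.68, adjusted p = 0.417), with antimiR array 7 at 6.76 and the other 4 between 3.37 and 4.20. The miR-31 targets had a median of -0.01 and an upward test direction (adjusted p = 0.875), with Egln3 at -0.38 (adjusted p = 0.768) and Stk40 at -0.01 (adjusted p = 0.982). Leaving out 1 array gave between 0 and 4 called genes: 4 without ZD array 15, and 1 without antimiR array 7 or ZD array 11, 13 or 14.

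After 20 weeks of antimiR, Ptgs2, Cxcl1, Sele and Adm were lower than in untreated ZD rats, and Egr2 and the retinoic acid hydroxylase Cyp26b1 were higher (n = 5 each). Ptgs2 fell by 3.88 (SE 0.68, adjusted p = 0.0137) to a mean of 3.09 (SD 0.37), near the ZS mean of 3.10 (SD 0.09). Both means lay well below the array medians of 5.37 to 5.45 and may be near background, which was not tested. Car2 fell by 2.90 (SE 0.65, adjusted p = 0.0292), Krt17 by 3.01 (SE 0.61, adjusted p = 0.02) and Krt6c by 2.65 (SE 0.52, adjusted p = 0.0191). On antimiR arrays 1 and 2 Car2 stood at 8.58 and 10.33, the latter inside the untreated ZD range of 8.59 to 11.67. On antimiR arrays 3 to 5 it stood between 5.84 and 6.49. The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 fell by 1.81 (SE 0.40) and 1.20 (SE 0.29), the endothelial proteoglycan gene Esm1 by 1.74 (SE 0.29, adjusted p = 0.00923), Adm by 1.47 (SE 0.29) and the amino acid transporter Slc6a20a by 1.28 (SE 0.20, adjusted p = 0.00478). The selectins Sele and Selp, which capture leukocytes on vessel walls, fell by 1.19 and 0.93. The activin subunit Inhba fell by 1.25, the complement regulator Cfi by 1.18, the pericyte gene Rgs5 by 1.01, the protease inhibitor Timp1 by 0.90 and Slc7a11 by 0.82. Vegfa (fell by 0.55), Ndrg1 (fell by 1.60) and Cxcl2 passed narrowly, at adjusted p = 0.04997, and each lost the threshold in 7 of the 10 fits that left out 1 array.

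The increases after 20 weeks were smaller. Cyp26b1 rose by 1.24 (SE 0.25), the zinc finger gene Egr2 by 1.07 (SE 0.16, adjusted p = 0.00478), the ceramidase Asah2 by 1.00, Bmp6 by 0.86, Tceal1 by 0.85, the epithelial transcription factor Elf5 by 0.70, the kinase Map2k6 by 0.62, the endocytic receptor Lrp2 by 0.59, Hyal3 by 0.56 and Cep70 by 0.55. For Egr2 and Bmp6 a second probe set lay at -0.02. In all 92 genes changed, 23 up and 69 down, of which 3 rose and 17 fell by at least 2-fold, and 2108 genes had an unadjusted p under 0.05. The share of increases was 25% here, 42.3% after median centring of the arrays, 42.2% with array weights and 36.4% without dim genes. It stayed at 25.8% with quantile normalization and 27.0% with trend and robust fitting. The miR-31 targets did not move as a list (median 0.03, adjusted p = 0.261): Egln3 was 0.63 (SE 0.23, adjusted p = 0.18), the Hippo kinase Lats2 0.44 (adjusted p = 0.0506) and Stk40 -0.05 (adjusted p = 0.841). S100a9 (-4.24, adjusted p = 0.0739), S100a8 (-3.06, adjusted p = 0.134) and Krt14 (-0.71, adjusted p = 0.0751) did not pass.

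The number of genes called after 20 weeks rested on single arrays. It was 379 without antimiR array 2 and 258 without ZD array 15, 52 without antimiR array 1, 27 without ZD array 14, 20 without antimiR array 5, 12 without antimiR array 3, and 9 without antimiR array 4 or ZD array 12. Ptgs2, Egr2, Esm1 and Slc6a20a passed in all 10 of these fits, and the other 22 of the 26 genes named by the rule lost the threshold in at least 2. Array weights gave 557 genes, including all 92, and a fit on the compared groups alone gave 21, of which 7 were among the 92. With the smooth muscle covariate 9 of the 26 genes passed, among them Ptgs2 and Egr2.

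NF-kB targets had a median of -0.23 after 20 weeks of antimiR, with 28 of 32 members below 0 (adjusted p = 3.29e-07, and adjusted p = 0.264 with an estimated correlation); 3 fell, and 14 adjusted over the list alone. Macrophage genes had a median of -0.58 (adjusted p = 7.17e-07, and adjusted p = 0.669 with an estimated correlation). None of those 20 genes passed over all genes with limma and 6 fell adjusted over the list alone, with the complement gene C1qa at -0.96 and the mannose receptor Mrc1 at -1.22. Hypoxia genes had a median of -0.26 (adjusted p = 5.61e-06, and adjusted p = 0.426 with an estimated correlation), with 3 of 27 down (8 adjusted over the list alone). Smooth muscle genes were higher with a median of 0.70 (adjusted p = 0.00012, and adjusted p = 0.778 with an estimated correlation), although no single member passed: Myh11 stood at 1.39 (SE 0.50, adjusted p = 0.179). With smooth muscle level itself as the covariate that median was 0.02 and the list did not pass.

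Endothelial genes had a median of -0.20 after 20 weeks (adjusted p = 0.027, and adjusted p = 0.843 with an estimated correlation), a call lost without antimiR array 2 or ZD array 13 or 15 (adjusted p from 0.0525 to 0.347), and its median ran from -0.40 with the smooth muscle covariate to -0.12 with array weights (adjusted p from 1.13e-06 to 0.347 over 20 alternatives). The basal keratin list had a median of -0.17 (adjusted p = 0.0321, and adjusted p = 0.78 with an estimated correlation), with Krt17 past the threshold; it was lost without antimiR array 1 or 2 or ZD array 11 or 12 (adjusted p from 0.0739 to 0.214), and its adjusted p ran from 0.00247 to 0.214 over 20 alternatives, with medians from -0.21 to -0.06. The cell cycle list had a median of 0.04, a mean of -0.05 and a test that did not pass (adjusted p = 0.52). It passed without ZD array 15 (median -0.30, adjusted p = 0.000125) and with array weights (median -0.15, adjusted p = 0.0249).

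Genes changed by the diet mostly went the other way after antimiR. Of the 1974 genes, 91.4% had the opposite sign after 20 weeks and 79.3% after 5 weeks. Of the 92 genes called after 20 weeks, 55 had risen on ZD and fell with antimiR (4.79 expected by n1 × n2 / N), 17 had fallen and rose (1.60 expected), and 0 changed in the same direction in both (limma). The first set includes Ptgs2, Car2, Krt6c, Krt17, Cxcl1, Adm and Vegfa, and the second Cyp26b1, Egr2, Bmp6 and Elf5. Both comparisons use the same untreated ZD arrays, which alone gives opposite signs, so the expected numbers above are not those of an antimiR without effect: simulated antimiR groups without an effect gave a median of 65.5%, with 86.1% at the upper end of the central 95% of draws, and a mean covariance across genes of -0.0147. The observed covariance of -0.0586 lay inside the central 95% of those draws, from -0.0630 to 0.0174. Array noise in the draws came from all 20 unedited arrays together, so a wider spread of the untreated ZD arrays is not in them. With the ZD arrays split so that no array served both comparisons, a median of 81.4% went the other way over the 10 splits (57.0% to 86.3%) after 20 weeks and 65.65% after 5 weeks. Simulated groups, each with a single split drawn at random, gave a median of 49.3% and 95% of their shares between 17.7% and 85.8%.

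**Figure D3:**
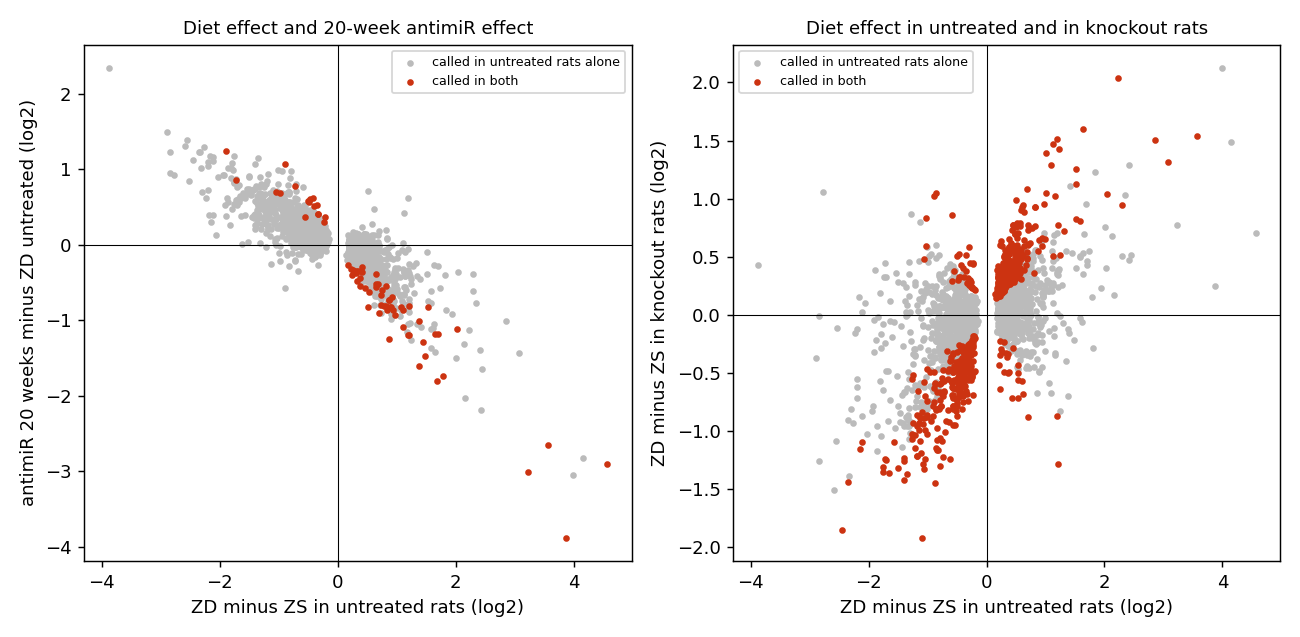
Each point is 1 of the 1974 genes changed on ZD in untreated rats, plotted as its ZD minus ZS change in log2 units against its change after 20 weeks of antimiR (left) and against ZD minus ZS in knockout rats (right); red points were called in both. On the left 91.4% of genes lie on opposite sides of 0, where the shared ZD arrays alone gave a median of 65.5% and up to 86.1% in the central 95% of draws, and on the right 73.8% lie on the same side.

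Between 20 and 5 weeks of antimiR 3 genes passed with limma (n = 5 each, and 868 had an unadjusted p under 0.05). Age at sampling may differ between these groups, since the labels leave it open for the 5-week rats. The inflammasome cytokine Il18 was higher after 20 weeks by 1.20 (SE 0.19, adjusted p = 0.00869), Ppp1r10, a nuclear regulator of protein phosphatase, was lower at -0.78 (SE 0.13, adjusted p = 0.00869), and the stress-responsive gene Csrnp1 was lower at -0.53 (SE 0.10, adjusted p = 0.0461). The count was 0 without antimiR array 4 or 5 of the 20-week group or array 7 of the 5-week group. It was 20 without 20-week array 2, 8 without 20-week array 1, 7 without 5-week array 10, and 5 without 5-week array 6 or 9. Il18 and Ppp1r10 lost the threshold in 3 of the 10 fits and Csrnp1 in 6. Cell cycle genes were higher after 20 weeks with a median of 0.44 (adjusted p = 1.99e-05, and adjusted p = 0.843 with an estimated correlation), a call lost without 5-week array 6 (median 0.27, adjusted p = 0.208); without 5-week array 9 the median was 0.70.

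Immediate early genes were lower after 20 than after 5 weeks with a median of -0.29 (adjusted p = 0.001, and adjusted p = 0.669 with an estimated correlation); 4 of 18 fell and 1 rose adjusted over the list alone, with Ccn1 at -1.51 and Klf2 at -0.77. NF-kB targets had a median of -0.15 (adjusted p = 0.00298, and adjusted p = 0.646 with an estimated correlation), lost without 5-week array 7 (adjusted p = 0.0791). Macrophage genes had a median of -0.22 (adjusted p = 0.00313, and adjusted p = 0.819 with an estimated correlation), lost without 5-week array 6 (adjusted p = 0.255). Endothelial genes had a median of -0.23 (adjusted p = 0.0197, and adjusted p = 0.819 with an estimated correlation), lost without 20-week array 2 or 5-week array 6 or 9 (adjusted p from 0.339 to 0.46) and with array weights (median -0.04, adjusted p = 0.93); its adjusted p ran from 0.00015 to 0.93 over 20 alternatives. Cornified envelope genes had a median of 0.06 (adjusted p = 0.0199, and adjusted p = 0.803 with an estimated correlation), lost without 20-week array 1 or 5-week array 9 (adjusted p of 0.0908 and 0.144).

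In miR-31 knockout rats the diet comparison asked what zinc deficiency changed without the microRNA (6 ZD and 4 ZS arrays). On ZD, Gadd45a, Klk10 and Ereg rose and Id3, Ccl21, Cd36 and Stab1 fell. The acyl-CoA thioesterase Acot1 rose by 1.63 (SE 0.51, adjusted p = 0.0239), Plaat5 by 1.55 (SE 0.36), the growth arrest gene Gadd45a by 1.51 (SE 0.33), Atp13a5 by 1.51, the serpin Serpinb7 by 1.48, Tmigd1 by 1.47, the kallikrein Klk10 by 1.43, Ocm by 1.39, the EGF family ligand Ereg by 1.29 (SE 0.23) and the kinase Rps6ka6 by 1.26 (SE 0.19). Id3, an inhibitor of helix-loop-helix factors, fell by 1.88 (SE 0.25, adjusted p = 1.46e-05). Myl9 fell by 1.85, the lymphatic chemokine Ccl21 by 1.85, the fatty acid transporter Cd36 by 1.79, the scavenger receptor Stab1 by 1.58, the class II antigen gene RT1-Db1 by 1.54, the purinergic receptor P2rx1 by 1.52, Ptp4a3 by 1.46 and Lrg1 by 1.45. Ptgs2 was 0.25 (SE 0.70, adjusted p = 0.84), Egln3 -0.09 (adjusted p = 0.834) and S100a8 2.12 (adjusted p = 0.133), and none of these passed.

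In knockout rats 3049 genes changed with the diet, 1347 up and 1702 down, and 39 rose and 127 fell by at least 2-fold. The share of increases was 44.2%, and 55.0% after median centring. Without ZS knockout array 32 the count was 1566. That array stood apart from the other 3 of its group, with a macrophage list mean of 9.62, a fibroblast list mean of 10.3 and a T and B cell list mean of 6.90. Of the 20 genes named by rank 17 passed in every fit leaving out 1 array. Acot1 and Myl9 lost the threshold without array 32, and Atp13a5 lost it in 8 of the 10 fits. Of all 79 called genes named by the rule, 55 passed in every fit leaving out 1 array and 43 with the smooth muscle covariate.

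Macrophage and antigen presentation genes were lower on ZD in knockout rats, with 13 of 20 down (16 adjusted over the list alone) and a median of -0.81 (adjusted p = 1.13e-07, and adjusted p = 0.64 with an estimated correlation). The complement gene C1qc fell by 1.44 and the receptor Csf1r by 0.90. Without array 32 the list median was -0.51 (adjusted p = 2.65e-05). Fibroblast and matrix genes fell in 10 of 22 (14 adjusted over the list alone), with Col6a2 at -1.20 (SE 0.18), Fn1 at -1.29 and Col1a2 at -1.08. Their median was -0.76 (adjusted p = 1.97e-05, and adjusted p = 0.692 with an estimated correlation), -0.44 without array 32 and -0.24 with the smooth muscle covariate (adjusted p = 0.0597, the highest over 20 alternatives). Smooth muscle genes fell in 7 of 14 (11 adjusted over the list alone), with Actg2 at -1.44 and Smtn at -1.36. Their median was -1.16 (adjusted p = 3.02e-05, and adjusted p = 0.713 with an estimated correlation), -0.97 without array 32 and 0.06 with smooth muscle level itself as the covariate.

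Endothelial genes fell in 4 of 12 (6 adjusted over the list alone), with Esam at -0.91 and Tie1 at -0.85, a median of -0.48 (adjusted p = 0.000394, and adjusted p = 0.677 with an estimated correlation), -0.24 without array 32 and -0.25 with the smooth muscle covariate. Interferon response genes fell in 7 of 22 (14 adjusted over the list alone), with the antiviral gene Mx1 at -1.04 and Ifi44l at -1.20. Their median was -0.47 (adjusted p = 0.00139, and adjusted p = 0.64 with an estimated correlation), -0.33 without array 32 and -0.26 without array 33. The T and B cell list had a median of -0.52 (adjusted p = 0.0167, and adjusted p = 0.843 with an estimated correlation). Cd3e, Cd8a and Cd2 fell, while 0 of 17 genes fell adjusted over the list alone. These 3 genes lost the threshold in 6, 6 and 7 of the 10 fits that left out 1 array. Without array 32 the list median was -0.02 (adjusted p = 0.995), and the list adjusted p ran from 0.000326 to 0.995 over 20 alternatives. Ifi44l lost the threshold without array 32 (adjusted p = 0.0663).

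Cornified envelope genes were higher on ZD in knockout rats, with 9 of 31 up (9 adjusted over the list alone) and none down. The list median was 0.22 (adjusted p = 0.000478, and adjusted p = 0.669 with an estimated correlation), and 0.07 without array 32. The transcription factors Klf4 and Grhl1 rose by 0.63 and 0.68, Sprr2d by 1.60 and Tmprss11d by 1.04. Immediate early genes rose in 5 of 18 and fell in 1 (7 and 1 adjusted over the list alone), with Junb at 0.89, Egr2 at 1.02 and Klf2 at -0.80. Their median was 0.35 (adjusted p = 0.00493, and adjusted p = 0.692 with an estimated correlation), and 0.20 with the smooth muscle covariate (adjusted p = 0.0461, the highest over 20 alternatives). Cell cycle genes had a median of 0.54 (adjusted p = 0.0028, and adjusted p = 0.964 with an estimated correlation), with the spindle motor Kif11 up by 1.07, a call lost without ZS array 32 or ZD array 38 (adjusted p up to 0.104). Without ZD knockout array 38, whose cell cycle mean of 8.81 lay above the 7.46 to 7.80 of its group, the median was 0.35 and the list did not pass (adjusted p = 0.0696). Hypoxia genes did not pass as a list (median -0.11, adjusted p = 0.215), with 4 of 27 down and none up, but passed with the smooth muscle covariate (-0.15, adjusted p = 0.0229). The miR-31 target list did not pass (median -0.02, mean 0.01, adjusted p = 0.889). NF-kB targets had a median of 0.03 and a downward test direction (adjusted p = 0.963). Of these 32 genes 2 rose, among them the receptor antagonist Il1rn at 1.16. A further 3 fell, among them the NF-kB subunits Rela and Nfkb1 at -0.32 and -0.36.

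More genes than expected for independent genes changed in the same direction on ZD in unedited and in knockout rats, which share no arrays. Of the 1974 genes changed in unedited rats, 73.8% had the same sign in knockout rats. Among genes called in both, 298 rose in both (93.4 expected by n1 × n2 / N) and 251 fell in both (118.3 expected), while 24 rose in unedited and fell in knockout rats (118 expected) and 35 did the reverse (93.6 expected). Across genes, which are not independent replicates, Pearson's r was 0.346. The expected numbers treat genes as independent, and no draws without an effect were made for this overlap. Noise in genes that move together could therefore also give such numbers. Atp13a5, Krt6c, Tmprss11d and Slc7a11 rose in both, and Myl9, Cyp1b1, Des and Actg2 fell in both.

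The diet by genotype interaction tested whether the diet effect differed in knockout rats (20 arrays). Knockout and unedited rats came from separate experiments, so a difference between genotypes and one between experiments cannot be told apart in it. It was below 0 for Ptgs2, Car2 and Vegfa, which rose on ZD in unedited rats, and above 0 for Aox4 and Adh6a, which fell there. The interaction subtracts the diet change of the same unedited arrays. Array noise in that change alone therefore favours opposite signs, and no draws without an effect were made for it. The interaction was -3.85 (SE 0.92, adjusted p = 0.012) for Car2 and -3.62 (SE 0.97, adjusted p = 0.0228) for Ptgs2. It was -2.50 for the interferon-inducible gene Slfn4, -2.37 (SE 0.36, adjusted p = 0.000385) for Id3, -2.10 for Olfm1, -2.08 for Ndrg1, -2.07 for Lyz2, -2.05 (SE 0.38) for Sele, -1.91 for RT1-Db1 and -1.87 for Plac8. Above 0 were Aox4 at 4.30 (SE 1.04, adjusted p = 0.0127), Adh6a at 3.83, Fxyd4 at 2.84, Prr15 at 2.42, Acot1 at 2.41, the claudin Cldn10 at 2.32, Cyp26b1 at 2.28 (SE 0.35, adjusted p = 0.000565), the steroid dehydrogenase Hsd11b2 at 2.17, Cryba4 at 2.14, P2rx2 at 2.08 and Egr2 at 1.92 (SE 0.23, adjusted p = 2.28e-05). A second probe set of Slfn4 lay at 0.07.

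The interaction passed for 1193 genes, 537 above 0 and 656 below, of which 87 and 132 exceeded 2-fold. The share above 0 was 45.0%, and 55.1% after median centring. Without ZS knockout array 32 the count was 615, of which 590 were among the 1193. Of the 20 genes named by rank 13 passed in all 20 fits leaving out 1 array, among them Car2, Ptgs2, Id3, Aox4 and Cyp26b1; Ndrg1 lost the threshold without array 32 alone, Hsd11b2 without array 32 or unedited ZD array 14, Fxyd4 without these or ZD array 13, and Lyz2 without array 32, ZS knockout array 31 or unedited ZS array 18. Cldn10, Acot1 and Prr15 lost it in 12, 11 and 13 of the 20 fits. With the smooth muscle covariate all 20 passed. Of all 60 called genes named by the rule, 33 passed in every fit leaving out 1 array. Mean Ptgs2 on ZD was 6.97 (SD 2.31) in unedited and 3.41 (SD 0.55) in knockout rats, against 3.10 and 3.16 on ZS. The knockout and ZS means may lie near background.

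Macrophage genes had an interaction median of -1.07, with 11 of 20 below 0 past the threshold (15 adjusted over the list alone; adjusted p = 1.04e-09, and adjusted p = 0.525 with an estimated correlation), and -0.72 without array 32. Hypoxia genes had a median of -0.51, with 10 of 27 below 0 (17 adjusted over the list alone; adjusted p = 1.13e-07, and adjusted p = 0.271 with an estimated correlation), among them Bnip3 at -1.55, Vegfa at -1.05 (SE 0.19), Eno1 at -0.97 and Pfkl at -0.83. Endothelial genes had a median of -0.79, with 5 of 12 below 0 (10 adjusted over the list alone; adjusted p = 7.69e-07, and adjusted p = 0.525 with an estimated correlation), among them Kdr at -1.12 and Flt1 at -0.86. Of these 5, Kdr, Tie1 and Flt1 lost the threshold without array 32. NF-kB targets had a median of -0.34, with 5 below and 1 above 0 (9 and 1 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.64 with an estimated correlation), among them the adhesion molecule Icam1 at -0.84, Ptges at -1.17 and Il1rn at 1.34; without array 32 that median was -0.20 (adjusted p = 0.00511). Cornified envelope genes had a median of 0.25, with 4 of 31 above 0 (6 adjusted over the list alone; adjusted p = 0.000394, and adjusted p = 0.669 with an estimated correlation).

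Of the remaining lists, fibroblast genes had an interaction median of -0.49 (adjusted p = 0.00235, and adjusted p = 0.819 with an estimated correlation), with Lox at -1.72 (SE 0.38); without array 32 it was -0.20 (adjusted p = 0.13), and with the smooth muscle covariate -0.77 (adjusted p from 1.18e-06 to 0.13 over 29 alternatives). T and B cell genes had a median of -0.59 (adjusted p = 0.00303, and adjusted p = 0.803 with an estimated correlation), with Ptprc at -1.75, and -0.10 without array 32 (adjusted p = 0.149); that call was also lost with array weights, and its adjusted p ran from 5.17e-05 to 0.149 over 29 alternatives. Interferon genes had a median of -0.32 (adjusted p = 0.014, and adjusted p = 0.692 with an estimated correlation), and -0.15 without ZS knockout array 33 (adjusted p = 0.132); that call was also lost without dim genes (adjusted p = 0.0527), and its adjusted p ran from 0.00164 to 0.132 over 29 alternatives. The miR-31 targets had a median of 0.07 (adjusted p = 0.0556), with Ppp6c at 0.60 (SE 0.11), Bap1 at 0.39, Arid1a at 0.48 and Axin1 at -0.38; Arid1a lost the threshold in 9 of the 20 fits. That list passed when unedited ZD array 12, unedited ZS array 16 or 17, ZS knockout array 30 or 32 or ZD knockout array 34 or 35 was left out (adjusted p from 0.0252 to 0.0488). The smooth muscle interaction median was 0.41 and did not pass (adjusted p = 0.247).

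**Figure D4:**
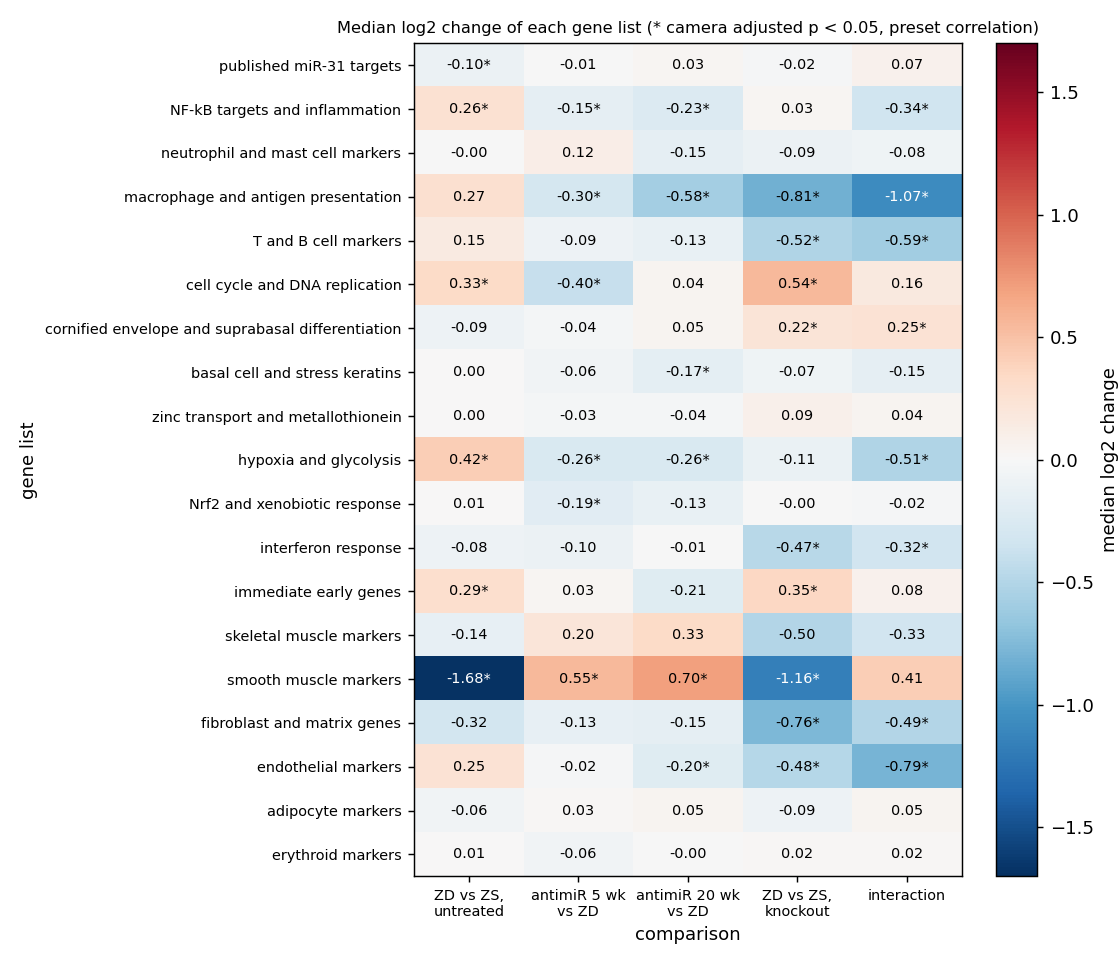
Cells give the median log2 change of the measured members of each of the 19 gene lists in 5 comparisons, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Hypoxia genes read 0.42 for ZD against ZS in unedited rats, -0.26 after 20 weeks of antimiR and -0.51 in the interaction, and no asterisk holds with an estimated correlation. All of these comparisons use the untreated ZD arrays, which alone favours opposite signs between the first and the others.

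Knockout rats were also compared with untreated rats on each diet, but experiment, genotype and normalization coincide in these contrasts and cannot be told apart. The median change over all genes was 0.26 on ZD and 0.25 on ZS, and changes here are given after subtracting it. On ZD 8128 genes were called with 90.0% increases, a share of 48.6% after joint quantile normalization and 23.4% after median centring. On ZS 8119 were called with 85.0% increases, a share of 49.75% and 27.2% under the same alternatives. On ZD the target gene Stk40 stood at 1.12 above the shift (1.05 and adjusted p = 4.26e-11 after quantile normalization), Egln3 at 0.78, Aox4 at 3.58, Upk1b at 3.92, Ccl11 at 3.37 and Cnn1 at 2.77, and Ptgs2 at -3.83, Stfa2l2 at -2.52, Sprr1b at -2.41 and Tubb3 at -2.34. The largest decrease there was Crisp3 at -5.70 (SE 2.16). On ZS Stk40 stood at 0.89, Tacr2 at 3.31, Id3 at 2.76 and Cd36 at 2.71, next to the skeletal muscle genes Acta1 at 3.03, Eno3 at 2.74, Smpx at 2.72, Myl3 at 2.71, Ckm at 2.66 and Tnnc2 at 2.61, and Serpinb7 at -2.10, Slurp1 at -1.90 and Il1rn at -1.77.

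Markers of other tissues were also higher in knockout than in untreated rats, here without subtracting the shift. On ZS 19 of 20 macrophage genes rose, with a list median of 1.58 (adjusted p = 0.000701, and adjusted p = 0.803 with an estimated correlation), and 12 of 12 endothelial genes, with one of 1.36 (adjusted p = 0.00122, and adjusted p = 0.713 with an estimated correlation). Skeletal muscle genes had a median of 2.03 and smooth muscle genes one of 1.48; neither list passed (adjusted p = 0.864 and 0.178), but both did after quantile normalization (adjusted p = 0.0284 and 0.00104). On ZD 14 of 14 smooth muscle genes rose, with a median of 2.08 (adjusted p = 0.0103, and adjusted p = 0.848 with an estimated correlation). A difference in tissue content between the experiments was not tested. Cornified envelope genes were lower on ZS (median -0.47, adjusted p = 8.79e-12, and adjusted p = 0.264 with an estimated correlation).

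The effects of 20 weeks of antimiR and of the knockout on ZD, measured against the same untreated arrays, had a covariance across genes of 0.0458, where simulated groups without an effect gave a mean of 0.0149 (central 95% from 0.000468 to 0.0341) and splits of the shared arrays a median of 0.0300. After 5 weeks the covariance was 0.0280, inside that range, with 0.0117 over the splits. The simulated knockout group was drawn around the untreated ZD mean. Its range therefore leaves out differences of experiment, normalization and tissue content, which coincide with genotype here. No simulated range was made for the splits, so a shared effect of antimiR and knockout cannot be concluded.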

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

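The tests of tissue share behind the smooth muscle genes were chosen only after the lower smooth muscle values had been seen, and so was the smooth muscle covariate, which the test of reversed genes uses; the predictions for the other tests were written before those tests were run.

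Single arrays stood far from the rest of their group for 13 of 168 group values tested, and chance alone gives about 1 in 20. Untreated ZS array 19 had a miR-31 target mean of 7.61 (others 7.53 to 7.55) and an erythroid mean of 4.37 (4.49 to 4.52). ZS array 17 had Ptgs2 at 3.26 (3.04 to 3.09) and ZS array 18 had Mki67 at 7.96 (8.43 to 8.62). In the 20-week antimiR group, array 2 had an NF-kB mean of 6.21 (5.83 to 5.89). Array 1 of that group had a basal keratin mean of 9.04 (9.34 to 9.41), Krt14 at 11.73 (12.40 to 12.55), an Nrf2 mean of 9.09 (9.23 to 9.27) and an erythroid mean of 4.66 (4.49 to 4.54). In the 5-week group, array 7 had Ptgs2 at 6.76 (3.37 to 4.20) and array 6 had Krt14 at 12.24 (12.61 to 12.70). ZD knockout array 38 had a cell cycle mean of 8.81 (7.46 to 7.80), and ZS knockout array 32 an endothelial mean of 8.47 (7.64 to 7.78).

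Differences between groups were tested directly in the diet by genotype interaction, with 1193 genes called, and in 20 against 5 weeks of antimiR, with 3 genes called. For 20 against 5 weeks, 6 of 100 splits of the arrays, the real one included, reached 3 genes, so that count does not show a difference. Genotype coincides with experiment in the interaction. There 8 lists passed with the preset correlation: macrophage (-1.07), endothelial (-0.79), T and B cell (-0.59), hypoxia (-0.51), fibroblast (-0.49), NF-kB (-0.34), interferon (-0.32) and cornified envelope genes (0.25). Between 20 and 5 weeks 6 lists passed: cell cycle (0.44), cornified envelope (0.06453), immediate early (-0.29), endothelial (-0.23), macrophage (-0.22) and NF-kB genes (-0.15). None of these passed with an estimated correlation.

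Other groupings of the same arrays were used to ask how many genes pass without the real grouping. Among 100 splits with the real one included, 1 reached the real count for diet in unedited rats (1974, highest other 310), diet in knockout rats (3049, highest other 472), knockout against untreated on ZD (8128, highest other 6794) and on ZS (8119, highest other 6404), and the interaction (1193, highest other 484). In the highest other split of knockout against untreated on ZD, the untreated arrays and knockout array 39 stood against the remaining knockout arrays. On ZS untreated arrays 17 to 20 stood against the knockout arrays and untreated array 16. Both nearly repeat the real grouping, and the median other split gave 0 genes. For 5 weeks of antimiR the real count was 0, which all 100 splits reach by definition, so it tests nothing (highest other 857). For 20 against 5 weeks 6 reached the real 3 (highest other 277). For 20 weeks of antimiR 4 reached the real 92. The highest other split there gave 1199 genes, several times the real count, which points to structure among these arrays: it exchanged antimiR array 2 with untreated ZD array 15 and left the other arrays in place, and its smooth muscle difference was 1.13 against 0.74 in the real grouping, its cell cycle difference -0.61 against -0.05. A treatment effect blurred by these 2 arrays would give such a rise as well (379 genes passed without array 2 and 258 without array 15), and no test separated it from a structure unrelated to treatment. The 92 genes are therefore best read together with their dependence on single arrays.

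Smooth muscle genes lower on ZD could come from less non-epithelial tissue in the ZD samples. In unedited rats the fibroblast and matrix median was -0.32 (95% interval over list members -0.46 to -0.14). This was smaller than 0.5 times the smooth muscle median at -0.84 (-1.17 to -0.54), and the endothelial median was 0.25. An even loss of all such tissue would lower these lists alike, so the values argue against it. The intervals resample genes that move together, not rats, so they do not exclude a lower share. In knockout rats the fibroblast median was -0.76 (-0.89 to -0.66), beside 0.5 times the smooth muscle median at -0.58, and the test left the explanation open. A lower share of smooth muscle alone may remain: 14 of 14 markers were below 0, which less muscle tissue and lower expression within muscle cells would both give, and these cannot be told apart here. No biological explanation was tested.

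Genes changed by ZD that went the other way after 20 weeks of antimiR could reflect the treatment, or the untreated ZD arrays that both comparisons share. Unsplit, 91.44% lay above the 86.06% that simulated groups without an effect reached at the upper end of their central 95% (median 65.47%). Those draws took array noise from all 20 unedited arrays together. A wider spread of the untreated ZD arrays is therefore not in them, and 86.06% is not a firm limit. With those arrays split, the median share was 81.38%, above the simulated median of 49.28% and inside its range of 17.74 to 85.82%. That range is of shares from a single random split per draw, not of medians over 10 splits, so the comparison cannot decide. Array-to-array noise stays open, and the part that shared arrays play in the unsplit share was not settled. With the smooth muscle covariate in both comparisons 79.03% of the 1974 genes called without it stayed reversed, and 96.13% of the 181 genes called with it. The limit of 60% written for that test was wrong, because the shared arrays alone give more, and draws without an effect were not made with the covariate, so smooth muscle share stays open too. The larger share with the 20-week group than with the 5-week group (79.33%) was not tested as a difference.

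Most called genes were higher in knockout than in untreated rats. After joint quantile normalization the share of increases was 48.61% on ZD and 49.75% on ZS. That met the prediction written beforehand for separate normalization, a near even share. The prediction cannot decide, because that step makes the distributions equal and gives a share near this whatever the cause. Median centring, which was not part of the prediction, gave 23.43 and 27.18%. Separate normalization, experiment and genotype coincide and cannot be told apart as the source of the skew. Single genes such as Stk40, at 1.05 on ZD after quantile normalization, may still differ by experiment or by genotype.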

How the results depend on the processing

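Across the alternatives, 17087 gene and list values were recomputed: 15724 kept their direction and their side of the threshold, 822 lost the threshold, 290 gained it, 243 that did not pass took another sign, and 8 reversed (1 gene, 7 lists). The cause was not tested unless stated. Quantile normalization gave 2 genes for 5 weeks of antimiR. Median centring gave a miR-31 target median of 0.1064 (camera adjusted p = 0.0415) in the interaction. In knockout against untreated rats on ZD, the skeletal muscle median was above 0 in the main fit too, at 1.574. Its test direction is relative to the other genes. That direction turned upward with quantile normalization (median 1.263), median centring (1.149) and skeletal muscle level as a covariate (1.55). The fibroblast direction there turned upward with median centring, with a median of 0.04433 against 0.4701 in the main fit. Leaving out dim genes gave 7 genes between 20 and 5 weeks. Array weights gave 557 genes for 20 weeks, 22 between 20 and 5 weeks, and a target median of 0.08166 (adjusted p = 0.0293) in the interaction. Fitting only the groups compared, with fewer arrays to estimate the variance, gave 21 genes for 20 weeks, 0 between 20 and 5 weeks (limma; 868 had an unadjusted p under 0.05 in the full fit), and target medians of -0.0229 in knockout rats, with the opposite test direction, and 0.07228 (adjusted p = 0.0396) in the interaction. The mean of all probe sets turned RT1-Bb in knockout against untreated ZD rats to -0.9079, since its probe sets disagree, and gave target medians of -0.024 (adjusted p = 0.0632) for diet in unedited rats and 0.07064 (adjusted p = 0.0481) in the interaction. Testing all probe sets, which are more in number, gave 5497 calls for diet in knockout rats, 17139 and 16391 for knockout against untreated on ZD and ZS, and 1968 in the interaction. Skeletal muscle level as a covariate gave 1 gene for 5 weeks.

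Of the alternatives chosen after seeing the data, the smooth muscle covariate gave 181 genes for diet in unedited rats, 39 for 20 weeks of antimiR and 1427 for diet in knockout rats. Smooth muscle level was itself lower on ZD, so calls lost for diet do not show that a change followed smooth muscle content. Target medians were -0.05806 (adjusted p = 0.213) for diet in unedited rats and -0.0148 for 5 weeks. It turned the fibroblast median in unedited rats to 0.4181 (adjusted p = 4.15e-05), and the smooth muscle median in knockout rats to 0.06273, the latter by construction. Only arrays of the same normalization set gave a target median of -0.0229 in knockout rats. Among the alternatives fixed beforehand, with an estimated correlation the target median for diet in unedited rats, -0.1006, did not pass (adjusted p = 0.577), and passing lists went from 49 to 0. Splitting the untreated ZD arrays gave reversed shares of 65.65% for 5 and 81.38% for 20 weeks and antimiR and knockout covariances of 0.01166 and 0.02996.

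Leaving out 1 array gave 1191 to 2424 genes for diet in unedited rats, 0 to 4 for 5 weeks, 9 to 379 for 20 weeks, 0 to 20 between 20 and 5 weeks, 1566 to 3244 for diet in knockout rats, 7729 to 7945 and 7469 to 7854 for knockout against untreated on ZD and ZS, and 615 to 1519 in the interaction. Target medians ran from -0.1333 to -0.0483 for diet in unedited rats, -0.01756 to 0.007875 for 5 weeks, 0.008584 to 0.0469 for 20 weeks, -0.02897 to 0.00735 in knockout rats and 0.04152 to 0.1017 in the interaction. The T and B cell median in knockout rats ran from -0.7435 to -0.02204, the latter without ZS knockout array 32, where the test direction reversed. The seed-site alternatives were not run. The number of arrays limits small changes: in simulated data 48% of changes of 0.5 log2 units were recovered in the interaction.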
